A study of Staphylococcus aureus with 4 samples.

How the data were processed

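The deposited table gave read counts of S. aureus NCTC 8325 for 2844 annotated loci (2767 coding, 16 ribosomal RNA, 61 tRNA), with sense and antisense reads counted separately. All 2844 matched the reference annotation (assembly ASM1342v1) by locus tag, and 446 had a symbol. The values are expected counts per the file headers and their fractions: the deposited counts are not whole, so a read that fits several places is shared out. Aligner, counter and trimming are not given in the sources used here. The authors compared the groups with DESeq 1.12.1, per the labels. In the authors' deposited table the group means are a normalised signal, the fold change is a ratio, its logarithm is in log2 units, and the test gives a p-value and an adjusted p-value over sense and antisense values together. A shorter deposited table held the 197 entries with an unadjusted p-value under 0.05.

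Each sample had a library not treated and a library treated with TEX (terminator exonuclease, which removes RNA with a 5' monophosphate in differential RNA-seq). The labels describe only the sample, so the untreated libraries, which the authors' comparison used, were the main measurement, and the TEX-treated libraries were kept as a separate measure. The table numbers the compound 59, which was taken to be compound 3 because the labels hold no other treated group and the authors compared no other with DMSO. The table holds 4 more columns of libraries, named compound1, that no label describes, and these were not used. Whether the labels' compound 3 is the table's compound 59 or its compound 1 cannot be settled from the files. Groups were compound 3 (2 libraries) and DMSO (2 libraries), with 1 comparison. Ribosomal RNA and tRNA loci were left out because their copies share reads.

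Expected counts of the 2767 coding loci were rounded and tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, no covariate) at a Benjamini-Hochberg adjusted p under 0.05. The filter left 2197 genes, and 570 were not tested. CPM values are counts scaled to TMM library sizes; fold changes use a prior count of 2 for the list tests. The biological coefficient of variation was 0.235. The 30 gene lists were matched by symbol or product name and tested with camera of limma 3.58.1 (correlation 0.01) if at least 3 members were measured, with the estimated correlation and fry beside it. A listed gene without a match counted as not measured, though its locus may be among the coding loci under another name. A match was found for 5 of 10 cytolytic toxin, 12 of 22 virulence regulator, 13 of 20 surface protein, 8 of 29 iron acquisition and 1 of 10 efflux genes. DESeq2 1.42.0 and limma-voom served as other tests, in R 4.3.3. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. A ratio for a gene with 1 to 3 counts in a group is over pooled counts scaled by library size, with an exact 95% binomial (Clopper-Pearson) interval.

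The comparison, the lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined. The rule named, among genes past the threshold with no overlap of the groups' libraries and a mean of at least 10 counts, the 12 largest rises and the 12 largest falls, with at most 3 from a run of neighbouring loci and at most 3 hypothetical proteins per direction. It always named agrA, agrB, agrC, hld, hla, spa, sarA, saeR, saeS, rot and sigB (agrD had no matching locus), and for each list up to 4 changed members or, with none, the 2 with the highest counts. It gave 87 genes. Counts of 18 named loci include bases that overlap a neighbour on the same strand (at most 75 nt), and no named gene had counts within 10% of another locus in all libraries.

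The alternatives were other scaling (DESeq2-style factors, total counts), other filters, ribosomal RNA and tRNA loci included, DESeq2, limma-voom, the replicate number as a block, leaving out each library in turn and stricter thresholds. Named genes were followed in only 9 of these planned settings. Limma-voom, the filter of at least 10 counts in 2 libraries, the added ribosomal RNA and tRNA loci and the stricter thresholds were applied to the numbers of changed genes alone. Thinning the DMSO libraries to the depth of the compound 3 libraries (21 random draws), a block with the numbers of 1 group crossed, the exonuclease-treated libraries, the exchange of TEX-treated and untreated labels in 1 group, both libraries of each sample summed at equal depth (21 random draws, each count a median over draws, so that risen and fallen need not add up) and the settings for genes named later were added after seeing the data. The sum is the same whichever library of a sample was treated with TEX. Genes of like expression are the 100 nearest in mean level. Replicate numbers did not pair the samples, since the deviations of replicate 1 from the group means correlated at -0.193 across genes between the groups. The libraries of a group were not copies of each other, with a chi-square per degree of freedom of 12.3 for DMSO and 3.88 for compound 3.

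The steps were tested on simulated data with the depths of these libraries and 2197 genes. edgeR recovered 57 of 100 genes changed 4-fold and 7 of 100 changed 2-fold, with 0 false calls, DESeq2 recovered 45 and 5 with 1 false call, and limma-voom 41 and 3. A moved list of 30 genes was found (camera adjusted p = 4.93e-16), and 0 of the other 28 lists were called. The simulated genes varied independently, so this does not bear on lists whose members vary together. Estimated correlations in the real libraries were 0.498 for protein quality control, 0.416 for cytolytic toxins, 0.367 for ribosomal proteins and 0.586 for the TCA cycle. The compound 3 libraries, with 102678 and 76765 coding counts, set the precision.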

Results

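Total RNA was sequenced from Staphylococcus aureus NCTC 8325, a laboratory strain, after 20 h of growth at 37 °C with 100 µM compound 3 or with its solvent DMSO. Compound 3 is a hydroxy amide studied as an inhibitor of virulence, and the deposited table, where the only treated group compared with DMSO is numbered 59, was read as holding it under that number. The table also has columns for a compound numbered 1 that no label describes, and the files do not settle which of the numbers is compound 3. There were 2 groups with 2 biological replicates each. The libraries not treated with the exonuclease TEX held 6245759 and 4916747 sense counts in compound 3 replicates 1 and 2, and 39754940 and 49947727 in DMSO replicates 1 and 2. Ribosomal RNA took 94.5% to 95.4% of these counts, which left 102678 and 76765 counts over coding loci with compound 3 and 1055140 and 955981 with DMSO. The median coding locus had 6 counts in each compound 3 library, against 51 and 35.5 in the DMSO libraries. The delta-hemolysin gene hld, which lies within RNAIII, took 16.4% to 18.9% of the coding counts of each library. Across genes, log2 CPM correlated with Pearson's r = 0.965 between the DMSO libraries and 0.817 between the compound 3 libraries, against 0.811 to 0.854 across groups; genes are not independent replicates.

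Transcripts of the chaperone genes dnaK, grpE, dnaJ and clpB and of 4 of 5 measured cytolytic toxin genes were lower with compound 3 in the libraries not treated with TEX. Only 5 of the 10 listed toxin genes had a matching locus. The chaperone gene dnaK fell 8.14-fold, from 23745 ± 5068 to 2919 ± 410 CPM, counts scaled by library size (SD, n = 2). The leukocidin gene hlgC fell 7.09-fold, from 443 ± 75.8 to 62.2 ± 1.25 (SD, n = 2), and the alpha-hemolysin gene hla fell 3.17-fold, from 798 ± 169 to 249.8 ± 55.7 (SD, n = 2). The quorum-sensing genes agrA and agrC did not pass the test there, at log2 fold changes of -0.14 and -0.06, but rose by 1.59 and 1.63 on the log2 scale in the TEX-treated libraries of the same samples. There 100 genes of like expression had a median of 1.05. Of 2197 genes tested, 99 rose and 133 fell. These counts were 227 and 77 when total counts set the scale and 299 and 186, each a median over 21 random draws, when the TEX-treated and untreated libraries of each sample were summed. Of the 99 risen genes 62 and of the 133 fallen genes 52 were annotated only as hypothetical proteins.

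The comparison addressed the mode of action of compound 3 through the transcripts that differed from DMSO. A gene counted as changed when edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, and 527 genes had an unadjusted p under that value. The libraries of the groups did not overlap for 230 of the 232 changed genes and for 1179 of the 2197 tested genes, where chance gives 33.3%. The median tested gene stood at a log2 fold change of 0.10, and the risen genes had a median mean count of 57.5 against 339 for the fallen genes. The test called 57 genes without DMSO replicate 2, 114 without DMSO replicate 1, 284 without compound 3 replicate 1 and 335 without compound 3 replicate 2. Of the 59 named genes past the threshold these settings ended the calls of 42, 24, 8 and 9, and none of them changed direction. On simulated data of this depth the test recovered 57 of 100 genes changed 4-fold and 7 of 100 changed 2-fold, so most 2-fold changes were not detectable.

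Of the 12 measured genes for protein quality control, which refold or degrade misfolded proteins, 7 fell, 1 rose and 4 did not pass. Adjusted over the list alone, 8 fell and 1 rose. The neighbouring genes grpE, dnaK and dnaJ fell together, while hrcA, directly upstream of grpE on the same strand, did not pass (edgeR adjusted p = 0.591). grpE, whose product exchanges nucleotide on DnaK, dropped from 3083 ± 552 to 384 ± 22.4 CPM (SD, n = 2), a log2 fold change of -3.01 ± 0.34 (SE) with an edgeR adjusted p = 4.56e-05. dnaK lies at 1592613 to 1594445 on the minus strand of the chromosome (assembly ASM1342v1), and its edgeR adjusted p was 7.09e-05. dnaJ fell by 2.82 ± 0.41 (SE) on the log2 scale (edgeR adjusted p = 0.000134). The disaggregase gene clpB, at 882636 to 885245 on the plus strand, fell 6.01-fold, from 12270 ± 3722 to 2041 ± 88.9 CPM (SD, n = 2; edgeR adjusted p = 0.00011). The genes mcsA, mcsB and clpC, which encode a protein arginine kinase with its activator and the ATPase of the Clp protease, had log2 fold changes of -2.17, -2.40 and -2.10, and were chosen after their values were seen. groES, also chosen after its value was seen, rose 3.57-fold (edgeR adjusted p = 0.0015) on 93 and 37 counts with compound 3 against 151 and 137 with DMSO. Its adjusted p was 0.0608 without DMSO replicate 1 and its log2 fold change 1.07 to 2.32 over the settings without 1 library. Its partner groEL stood at -0.72 (edgeR adjusted p = 0.196), clpP at -0.77, clpX at -0.56 (-1.21 to -0.16 over these settings) and the repressor gene hrcA at -0.33, which became 0.16 when total counts set the scale. The list's median log2 fold change was -2.14, or -2.24 relative to the median tested gene, and camera with the preset correlation gave it an adjusted p of 1.13e-05. With the correlation estimated from these libraries, the list's adjusted p was 0.793. In the TEX-treated libraries of the same samples dnaK and grpE also fell, by 0.71 and 0.89 on the log2 scale, while clpB stood at -0.33 and dnaJ at -0.65 without passing. There clpP and clpX rose by 1.08 and 1.39 (edgeR adjusted p = 0.0036 and 0.000409), which is 0.0144 and 0.99 above genes of like expression, and hrcA fell by 1.56 (0.000275) on the log2 scale, while groEL stood at 0.32, groES at -0.18, mcsA at -0.36, mcsB at -0.33 and clpC at -0.12 without passing.

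Of 10 listed cytolytic toxin genes 5 had a matching locus, and of these 4 fell and 0 rose, as when adjusted over the list alone. The gamma-hemolysin and leukocidin genes hlgA, hlgC and hlgB, which lie side by side from 2489229 to 2492652 on the plus strand, fell 4.98-fold, 7.09-fold and 4.37-fold, with edgeR adjusted p-values of 0.000874, 0.000157 and 0.00117. hla, at 1076413 to 1077372 on the minus strand, had an edgeR adjusted p = 0.00309. Without DMSO replicate 2 the adjusted p was 0.116 for hla and 0.0729 for hlgB. Over the settings without 1 library the log2 fold change of hlgA ran from -3.26 to -1.79. hld stood at -0.47 ± 0.46 (SE) on the log2 scale (edgeR adjusted p = 0.585), and at 0.02 when total counts set the scale. The list's median was -2.13, with a camera adjusted p of 0.000992 and an adjusted p of 0.793 with the estimated correlation. In the TEX-treated libraries none of hla, hlgA, hlgB and hlgC passed the edgeR test, with log2 fold changes from -0.42 to -0.15, and hld rose by 0.74 on the log2 scale (edgeR adjusted p = 0.0365) where genes of like expression had a median of 1.10.

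In the untreated libraries none of the 4 measured agr genes, which include hld, passed the test, over all genes or adjusted over the list alone (0 rose and 0 fell). agrB stood at 0.83 ± 0.35 (SE) with an edgeR adjusted p = 0.144, agrC at -0.06 ± 0.32 (0.947) and agrA at -0.14 ± 0.32 (0.847). Scaling by total counts moved the median tested gene by 0.47 and turned agrA and agrC to 0.35 and 0.44. In the TEX-treated libraries agrA, agrB and agrC rose by 1.59, 1.40 and 1.63 on the log2 scale (edgeR adjusted p = 0.000156, 0.000402 and 0.000137), which is 0.54, 0.35 and 0.58 above genes of like expression. The sensor and regulator genes saeS and saeR, which drive toxin transcription, stood at -0.02 and 0.05, and the stress sigma factor gene sigB at 0.12. Of 22 listed virulence regulator genes 12 had a matching locus. Of the 11 tested 1 rose and 2 fell, as when adjusted over the list alone. rot, which encodes a repressor of toxins, fell 3.73-fold, from 390 ± 52.7 to 103 ± 40.9 CPM (SD, n = 2; edgeR adjusted p = 0.00297, and 0.105 without DMSO replicate 2), with a log2 fold change from -2.52 to -1.51 over the settings without 1 library. The global regulator gene sarA dropped by 1.00 ± 0.31 (SE) on the log2 scale (edgeR adjusted p = 0.0389, and 0.272 without DMSO replicate 2), and the sensor kinase gene lytS rose by 1.21 (0.0337, and 0.537 without it). Neither sarA nor lytS passed without DMSO replicate 1 or without compound 3 replicate 2. With TEX treatment sarA rose by 1.04 (edgeR adjusted p = 0.0031; 1.07 for genes of like expression) and lytS fell by 1.45 (0.000638) on the log2 scale, and rot stood at 0.36 (0.264). Camera gave the agr list an adjusted p of 0.997, with a median of -0.10, a mean of 0.04 and a test direction of higher, while fry's test for change in either direction gave it 0.0431. The regulator list had a median of -0.35 and an adjusted p of 0.377.

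Of 11 surface protein genes 2 rose and 2 fell, and 3 rose and 3 fell adjusted over the list alone (median 0.47, camera adjusted p = 0.964). The adhesin genes sdrC and sdrD rose by 1.30 and 1.27 on the log2 scale. spa, which encodes the immunoglobulin-binding protein A, fell 2.55-fold, from 1544 ± 469.9 to 599.5 ± 268 CPM (SD, n = 2; edgeR adjusted p = 0.0165), and the elastin-binding gene ebpS fell 2.37-fold (0.0123). Over the settings without 1 library the log2 fold change of spa ran from -2.02 to -0.90. Without DMSO replicate 2 the adjusted p was 0.332 for spa, 0.12 for ebpS, 0.499 for sdrC and 0.155 for sdrD, and without DMSO replicate 1 it was 0.0943 for sdrC and 0.226 for sdrD. Without compound 3 replicate 1 sdrC had 0.068. With TEX treatment sdrC, sdrD and ebpS rose by 1.48, 2.07 and 1.30 on the log2 scale, and spa stood at 0.64 (edgeR adjusted p = 0.0727). Genes of like expression had medians of 0.47, 0.84, 0.97 and 1.01 there. None of the 8 measured secreted enzyme genes passed, over all genes or adjusted over the list alone (median -0.42, camera adjusted p = 0.488), and the lipase genes SAOUHSC_00300 and SAOUHSC_03006 stood at -0.34 and -0.97. Of the 18 listed immune evasion genes 15 had a matching locus, and ecb, scn and adsA had none. The fibrinogen-binding protein-like gene SAOUHSC_01110, which rose 5.32-fold, was not matched to this list. None of the 9 measured immune evasion genes passed, over all genes or adjusted over the list alone (median 0.37, camera adjusted p = 0.347). Among them sbi stood at -0.83 and the superantigen-like gene SAOUHSC_00395 at 0.25. The same held for the 12 capsule genes (median 0.66, camera adjusted p = 0.485), where capD stood at 0.74 and SAOUHSC_00120 at 0.15, and for the 7 SigB regulon genes (median 0.14, camera adjusted p = 0.649), where asp23 stood at -0.44 and spoVG at -0.02.

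Among 49 ribosomal protein genes 8 fell and 1 rose, and 11 fell and 2 rose adjusted over the list alone. The largest falls rested on few counts. rplJ had 2 counts over both compound 3 libraries against 153 with DMSO, a depth-scaled ratio of 0.107 (95% counting interval 0.0129 to 0.394). rpsD had 3 counts against 190, a ratio of 0.13 (0.0265 to 0.384), and rplM fell by 1.98 on the log2 scale. Without DMSO replicate 2 rplJ, rpsD and rplM had adjusted p-values of 0.122, 0.232 and 0.487, and without DMSO replicate 1 of 0.13, 0.0702 and 0.12. The L7Ae-like gene SAOUHSC_00526 rose 4.43-fold on 9 and 10 counts (edgeR adjusted p = 0.0291), but did not pass without DMSO replicate 1 (0.355), DMSO replicate 2 (0.162) or compound 3 replicate 2 (0.086). The list's median was -0.53, with a camera adjusted p of 0.00191 and an adjusted p of 0.793 with the estimated correlation, and camera gave 0.497 without compound 3 replicate 2 and 0.0606 without DMSO replicate 2. Of 8 housekeeping genes only the gyrase subunit gene gyrB passed, falling 2.33-fold (edgeR adjusted p = 0.0139, and 0.199 without DMSO replicate 2), and 2 fell adjusted over the list alone (median -0.48, camera adjusted p = 0.0645). No tRNA synthetase gene of 20 passed, over all genes or adjusted over the list alone (median 0.22, camera adjusted p = 0.649), with SAOUHSC_01666 at -0.97 and thrS at -0.67.

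In central metabolism, 4 of 13 genes of the TCA cycle fell and 0 rose, and 6 fell adjusted over the list alone. The isocitrate dehydrogenase gene icd fell 2.84-fold, from 3992 ± 636 to 1409 ± 357 CPM (SD, n = 2; edgeR adjusted p = 0.0044, and 0.0688 without DMSO replicate 2), and acnA, sucC and sucD had log2 fold changes of -1.15, -1.15 and -0.99, where that of sucC ran from -1.93 to -0.67 over the settings without 1 library. The list's median was -0.61, with a camera adjusted p of 0.00235 and 0.793 with the estimated correlation, and it was 0.229 without compound 3 replicate 2 and 0.0539 without DMSO replicate 2. Of 12 glycolysis genes 3 fell and 1 rose, and 4 fell and 2 rose adjusted over the list alone (median -0.80, camera adjusted p = 0.0645). gapA, which encodes glyceraldehyde-3-phosphate dehydrogenase, fell 5.59-fold on 8 and 7 counts with compound 3 (edgeR adjusted p = 0.000464), glk and fbaA fell by 1.15 and 1.09 on the log2 scale, and the class I aldolase gene fda rose 2.3-fold. The acetoin reductase gene SAOUHSC_00086 fell 7.43-fold, from 6376 ± 1282 to 858 ± 36.1 CPM (SD, n = 2; edgeR adjusted p = 4.56e-05). Of 11 anaerobic genes 2 fell, as when adjusted over the list alone: pflA, the activator of pyruvate formate-lyase, fell 4.28-fold (edgeR adjusted p = 0.000366) and pflB fell 2.36-fold (median -0.0035, camera adjusted p = 0.377). Of 16 genes for respiration and ATP synthase 2 fell and 1 rose, and 3 fell and 1 rose adjusted over the list alone (median -0.07, camera adjusted p = 0.683). The quinol oxidase genes qoxB and qoxC fell by 1.67 and 1.27 on the log2 scale while qoxD of the same operon rose by 1.33, and without DMSO replicate 2 the adjusted p-values were 0.122, 0.511 and 0.129. Without the same library acnA, sucC, sucD, glk, fbaA, fda and pflB did not pass either (0.17 to 0.545), while gapA, pflA and SAOUHSC_00086 passed with each library left out. Without DMSO replicate 1 sucC, sucD, glk, fbaA, fda and qoxD did not pass, without compound 3 replicate 1 glk, fda and qoxD, and without compound 3 replicate 2 sucC, sucD and qoxC. The TEX-treated libraries gave called rises for pflA by 2.22, pflB by 1.80, fbaA by 1.08, sucD by 0.95 and qoxD by 2.25 on the log2 scale, where genes of like expression had medians of 1.05, 1.02, 1.01, 1.08 and 0.42. They did not call icd, acnA, sucC, gapA, glk, fda, qoxB, qoxC or SAOUHSC_00086.

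The largest rise by the rule for named genes was that of SAOUHSC_00979, a hypothetical protein gene at 951200 to 951751 on the plus strand. It rose 10.1-fold, from 31.8 ± 7.86 to 323 ± 100.4 CPM (SD, n = 2; edgeR adjusted p = 7.36e-05), on 45 and 24 counts with compound 3. The Cro-like gene SAOUHSC_02083 rose 7.79-fold, from 90.2 ± 0.79 to 698 ± 451 CPM (SD, n = 2), and the repressor-like gene SAOUHSC_02234 rose 8.49-fold on 21 and 15 counts. SAOUHSC_01110, annotated as a fibrinogen-binding protein-like gene, rose 5.32-fold on 175 and 67 counts, and the glutamine synthetase repressor gene SAOUHSC_01285 rose 4.85-fold on 140 and 46 counts. These 5 genes passed the threshold in each of the 9 planned settings, with log2 fold changes that ran over the settings without 1 library from 2.84 to 3.65 for SAOUHSC_00979, 1.94 to 3.54 for SAOUHSC_02083, 2.84 to 3.24 for SAOUHSC_02234, 1.60 to 2.90 for SAOUHSC_01110 and 1.32 to 2.83 for SAOUHSC_01285. The ribonucleotide reductase regulator gene nrdR rose 5.05-fold, the ABC transporter gene SAOUHSC_00731 5.28-fold, SAOUHSC_02226 8.82-fold, SAOUHSC_00415 7.49-fold and SAOUHSC_02232 4.22-fold, each of which did not pass without DMSO replicate 2 (adjusted p from 0.0701 to 0.199). Over the settings without 1 library the log2 fold changes ran from 1.39 to 4.45 for SAOUHSC_02226, with 210.34 and 42.08 CPM in compound 3 replicates 1 and 2, from 2.43 to 3.37 for SAOUHSC_00415, 1.85 to 2.76 for SAOUHSC_00731, 1.54 to 2.82 for nrdR and 1.76 to 2.44 for SAOUHSC_02232. Without compound 3 replicate 1 nrdR, SAOUHSC_00731 and SAOUHSC_02226 had adjusted p-values of 0.1, 0.0807 and 0.497, and without DMSO replicate 1 nrdR, SAOUHSC_00731 and SAOUHSC_02232 had 0.0721, 0.0987 and 0.129. Among the largest falls, SAOUHSC_01513 had 1 count over both compound 3 libraries against 231 with DMSO, a ratio of 0.0355 (95% counting interval 0.000895 to 0.2), and an adjusted p of 0.162 without DMSO replicate 2. SAOUHSC_02566 fell 5.47-fold, with an adjusted p of 0.155 without DMSO replicate 2, and SAOUHSC_02412 fell 7.78-fold (log2 fold change from -3.40 to -2.31 over the settings without 1 library) but overlaps tRNA loci on its strand over 75 and 38 of its 117 nt. With TEX treatment SAOUHSC_02412 rose by 1.19 on the log2 scale (edgeR adjusted p = 0.00141), where genes of like expression had a median of 1.05. Intervals cover counting error only.

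Of 30 amino acid synthesis genes 2 rose and 0 fell, as when adjusted over the list alone (median 0.66, camera adjusted p = 0.0645). They were the neighbouring histidine genes hisF, from 415 ± 68.1 to 1588 ± 313 CPM (SD, n = 2), and hisA, from 392 ± 70.3 to 1454 ± 235 (SD, n = 2), with edgeR adjusted p-values of 0.000349 and 0.000394. In the TEX-treated libraries hisF and hisA stood at 0.11 and 0.48 without passing, 0.96 and 0.50 below genes of like expression. With both libraries of each sample summed, camera called the amino acid list lower (adjusted p = 0.000411). Of 5 urease genes ureA rose 5.87-fold on 4 and 14 counts, also adjusted over the list alone (median 0.61, camera adjusted p = 0.255), with adjusted p-values of 0.529 without compound 3 replicate 2, 0.303 without DMSO replicate 2 and 0.122 without DMSO replicate 1, a log2 fold change from 1.27 to 3.16 over the settings without 1 library and one of -4.02 in the TEX-treated libraries. Of 25 genes with phage in their product name 2 rose and 2 fell, and 5 rose and 3 fell adjusted over the list alone (median 0.46, camera adjusted p = 0.377). Whether they lie in a prophage was not checked. Beside the Cro-like gene SAOUHSC_02083, the dUTPase gene SAOUHSC_01552 rose by 2.33, the phage infection protein gene SAOUHSC_02978 fell by 1.98 and SAOUHSC_00349 fell by 1.77 on the log2 scale, and the last 3 had adjusted p-values of 0.265, 0.0504 and 0.518 without DMSO replicate 2. SAOUHSC_01552 did not pass without any one of the libraries, and SAOUHSC_00349 did not pass without DMSO replicate 1 or compound 3 replicate 2. None of the 4 arginine deiminase genes passed over all genes, while 3 rose adjusted over the list alone (median 1.59, camera adjusted p = 0.0645), with arcA at 1.84 (edgeR adjusted p = 0.104) and arcD at 1.37 (0.0905). Camera called the arginine deiminase list without the filter (adjusted p = 0.0454), with the replicate block (0.02) and without compound 3 replicate 1 (0.00999) or DMSO replicate 1 (0.00566), but gave 0.497 without compound 3 replicate 2, 0.222 without DMSO replicate 2 and 0.793 with the estimated correlation. The TEX-treated libraries had falls of arcA by 2.45 and of arcD by 2.85 on the log2 scale. Of 12 fatty acid synthesis genes accC rose 3.73-fold, also adjusted over the list alone (median -0.03, camera adjusted p = 0.649), with an adjusted p of 0.118 without DMSO replicate 2.

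Few genes fell in 4 other lists. msrB, which encodes a methionine sulfoxide reductase, fell by 1.30 on the log2 scale and was the only one of 13 oxidative and thiol stress genes to pass, over all genes or adjusted over the list alone (median -0.38, camera adjusted p = 0.0823). recN fell by 1.34 as 1 of 6 SOS genes, where 2 fell and 1 rose adjusted over the list alone (median -0.29, camera adjusted p = 0.347). carB fell by 1.29 as 1 of 8 pyrimidine genes, also adjusted over the list alone (median 0.01, mean 0.07, test direction lower, camera adjusted p = 0.831). isaA and cidC fell by 1.93 and 1.17 among 6 autolysis and murein turnover genes, where 2 fell and 1 rose adjusted over the list alone (median -0.27, camera adjusted p = 0.555). Without DMSO replicate 2 none of these 5 genes passed, with adjusted p-values of 0.439, 0.149, 0.184, 0.338 and 0.497, and without DMSO replicate 1 only isaA did. No gene passed, over all genes or adjusted over the list alone, among 11 purine genes (median 0.55, camera adjusted p = 0.438; purL 0.55, purA 0.23), 7 cell wall stress genes (median 0.03, mean -0.30, test direction lower, camera adjusted p = 0.44; sgtB -0.44, pbp2 -1.02), 7 iron acquisition genes (median -0.62, camera adjusted p = 0.194; fhuB -0.62, sirB -0.85) and 5 lactose genes (median 0.76, camera adjusted p = 0.377; lacR 0.59, lacE -0.04). The efflux gene norA was the only 1 of 10 listed efflux genes with a matching locus and stood at 0.79 (edgeR adjusted p = 0.209).

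Of 29 lists tested, camera with the preset correlation called the 4 that hold protein quality control, cytolytic toxin, ribosomal protein and TCA cycle genes, each in the direction of lower, also when total counts set the scale. With the estimated correlation it called 0, and 0 had an unadjusted p under 0.05. By fry, which tests whether a list's genes move on balance in 1 direction, 0 lists passed and 3 had an unadjusted p under 0.05 (lowest adjusted p 0.262), while 7 passed its test for change in either direction.

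The TEX-treated libraries bear on how far these changes reach. The effect of TEX, TEX-treated over untreated library of a sample, correlated across 1263 genes with a mean of at least 50 counts at 0.913 between the DMSO replicates and 0.54 between the compound 3 replicates, but at -0.734 to -0.537 across groups. Fold changes in the TEX-treated libraries followed expression, with a median of 0.59 in the most expressed part of the genes. Of the 59 named genes past the threshold, the TEX-treated libraries called 15 in the same and 13 in the opposite direction and did not call 31. The 13 were pflA, pflB, fbaA, sucD, sarA, lytS, ebpS, msrB (1.32 there), gyrB (0.67), ureA, SAOUHSC_02412, SAOUHSC_02978 (0.77) and SAOUHSC_01552 (-1.96). Of these, gyrB, SAOUHSC_02978, sucD and sarA stood 0.37, 0.19, 0.12 and 0.02 below genes of like expression. Relative to such genes they were thus not opposite to the untreated libraries. The rest of the 13 stayed opposite on that measure, fbaA and SAOUHSC_02412 by only 0.07 and 0.14. Of the 28 other named genes the TEX-treated libraries called 11 higher and 9 lower, among them saeS, saeR and sigB at 0.96, 1.08 and 0.97. Summing both libraries of each sample at equal depth removes the distinction between the library types, and then 79 of the 99 risen and 32 of the 133 fallen genes passed in the same direction. dnaK, grpE, dnaJ, clpB, hla, hlgA, hlgB and hlgC were among the fallen genes that passed, with log2 fold changes of -1.71, -1.76, -1.62, -1.30, -0.79, -1.10, -1.04 and -1.51. The named genes spa, rot, SAOUHSC_00731, recN, cidC, carB, rplM, glk, icd, sucC, acnA, qoxB, qoxC, SAOUHSC_01552, SAOUHSC_02978 and gyrB no longer passed, and ureA, sarA, ebpS, lytS, msrB, pflA, pflB, fbaA and sucD changed sign without passing. Camera then gave adjusted p-values of 0.0603 for protein quality control, 0.122 for cytolytic toxins, 0.883 for ribosomal proteins and 0.171 for the TCA cycle, so that none of these 4 lists passed.

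**Figure D1:**
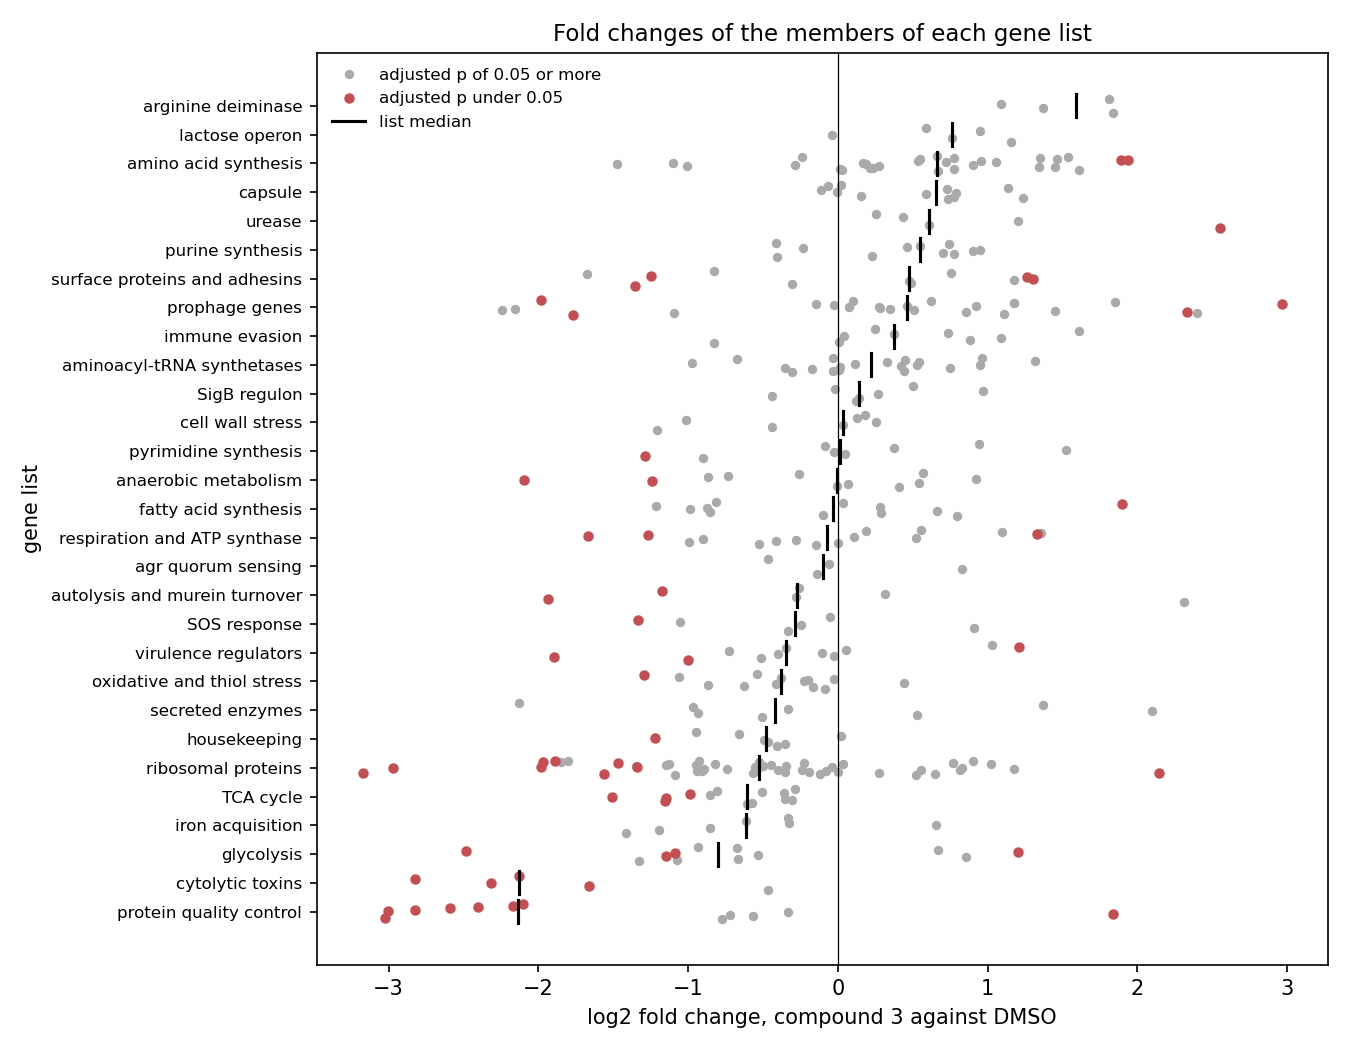
Log2 fold change of compound 3 against DMSO for each measured member of the 29 tested lists (one row per list); points are genes, red with an edgeR adjusted p under 0.05, and bars are list medians. The medians of protein quality control and cytolytic toxins lie at -2.14 and -2.13.

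Antisense reads made up 17.5% and 22.1% of the reads over coding loci with compound 3 and 11.3% and 8.26% with DMSO. These shares were 14.6% and 14.9% with compound 3 and 23.4% and 18.1% with DMSO in the TEX-treated libraries of the same samples. Of 697 loci tested for antisense counts 6 rose and 9 fell by edgeR's test, and 54 had an unadjusted p under 0.05. The number of changed loci was 7 with scaling factors from the sense counts, 7 without compound 3 replicate 2, 2 without DMSO replicate 2 and 0 without either of the remaining libraries. Antisense counts over the hypothetical protein gene SAOUHSC_01568, chosen after its values were seen, were 37 and 14 with compound 3 against 14 and 20 with DMSO (log2 fold change 3.42, edgeR adjusted p = 3.63e-06). Those over the cation transporter gene SAOUHSC_02874, chosen in the same way, were 1 and 1 against 187 and 436.

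The authors' deposited table held 21 coding genes with an adjusted p under 0.05 for sense reads, 21 lower and 0 higher with compound 3. All 21 of the authors' deposited table were among the 232 genes called by edgeR's test, with the same direction, and at an adjusted p under 0.01 the shared number was 10 of 10. The authors' DESeq test did not call clpB, hla, hlgA, hlgB or rot (adjusted p = 0.111, 0.531, 0.512, 0.481 and 0.272), while it called dnaK, grpE, dnaJ and hlgC. At an unadjusted p under 0.05 the authors' deposited table held 155 coding genes, 117 lower and 38 higher. Log2 fold changes of the authors' deposited table and of edgeR correlated with Pearson's r = 0.999 and Spearman's rho = 0.999 across 2195 genes, which are not independent replicates, and both come from the same libraries.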

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

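The correlation under thinning and the strand test reported here were written down before their values were known; the comparison by expression level, the interaction test and all measures for an exchange of library labels were chosen only after the result was seen.

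The TEX-treated libraries of the same samples, which the main comparison did not use, held a signal of their own: 588 genes rose and 773 fell with compound 3 among 2490 tested by edgeR, against 99 and 133 in the untreated libraries. The pyruvate formate-lyase activator gene pflA fell by 2.10 on the log2 scale in untreated libraries and rose by 2.22 in TEX-treated ones (edgeR adjusted p = 3.53e-05), while SAOUHSC_01285 rose by 2.28 and by 4.13 and SAOUHSC_02083 by 2.96 and by 2.85. Of the 133 genes that fell in untreated libraries 42 rose and 10 fell in TEX-treated ones, and of the 97 risen genes with a value there 53 rose and 11 fell. Across 2182 genes the fold changes of both library types correlated at Pearson's r = -0.135 and Spearman's rho = -0.175, with genes not independent replicates, and an interaction test called 1080 genes. The TEX fold change moved with expression, with medians of -1.43, -0.28 and 0.59 in the lowest, middle and highest parts of the genes by mean level. Set against genes of like expression, 94 of the 133 fallen genes stood lower there and 69 of the 97 risen genes higher.

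Thinning the TEX-treated DMSO libraries left the correlation at -0.132 (range over draws -0.141 to -0.126), under the 0.5 set for greater depth of these libraries as the cause. Random thinning keeps the expected ratio of the groups, so it could hardly raise the correlation that far. Depth as the cause of these other fold changes therefore stayed open. Background reads from both strands in the TEX-treated DMSO libraries stayed open: over the 773 fallen genes the antisense loss was 0.451 of the sense loss (95% bootstrap interval 0.311 to 0.627), on both sides of the 0.5 that had been set. That interval resampled genes and leaves out variation between libraries, and the genes were chosen for their sense loss in the same libraries. An exchange of the TEX-treated and untreated columns of 1 group met the expectation set for it after the result was seen, but is not settled by it. The antisense share was higher in the TEX-treated library for 2 of 4 samples, both DMSO replicates (11.3% to 23.4% and 8.26% to 18.1%). It was lower in both compound 3 replicates (17.5% to 14.6% and 22.1% to 14.9%). The coding share rose in 3 of 4 samples (-0.6 to 1.62 percentage points) and moved both ways in DMSO. The effect of TEX correlated across 1263 genes at 0.913 and 0.54 within groups and -0.734 to -0.537 across them, from which it follows that fold changes with exchanged labels correlated at 0.705 (-0.102 between library types as deposited), and TEX-treated compound 3 libraries were closer to untreated DMSO libraries (0.87 to 0.918) than the shallower untreated ones were (0.818 to 0.859). The opposite effects of TEX may come from an exchange, in which case untreated fold changes mix the effects of compound 3 and of TEX, or from an effect of compound 3 on primary transcripts that differs from that on processed ones.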

How the results depend on the processing

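Thinning, the crossed block, the exchanged labels, the summed libraries and the settings for genes named later were chosen only after the result was seen. Of the 59 named genes past the threshold, 17 (among them dnaK, grpE, dnaJ, clpB, hlgC, hlgA, gapA, pflA, hisF and hisA) kept their side in all 9 planned settings and 0 changed direction in these; DESeq2 lost 12, the replicate block 15, total counts 13 and leaving out DMSO replicate 2 lost 42, with fewer samples. Total counts gave 227 risen and 77 fallen genes, since they move the median gene by 0.47; thinning moved it by 0.13 with 927 genes tested and 212 changed, 174 of them shared. DESeq2 gave 65 risen genes. The replicate block gave 65 risen, and with crossed numbers 363 genes changed, 163 risen and 200 fallen; the cause was not tested. An adjusted p under 0.01 gave 111 genes, 52 risen and 59 fallen. Leaving out a library gave 57 to 335 genes (26 to 185 risen, 31 to 198 fallen), 2 to 9 lists and 0 to 7 antisense loci, where a lone library is assumed to vary like the other group. The estimated correlation left 0 lists, while the protein quality control and toxin lists passed in every other setting but the labels exchanged in DMSO (0.227 and 0.457) and the summed libraries (0.0603 and 0.122), and the ribosomal protein list did not pass with thinning (0.141). Antisense calls were 7 with sense scaling, and 10 calls were shared with the authors' deposited table at the 0.01 threshold, by construction. Reversed values were with total counts agrA 0.35, agrC 0.44, hld 0.0224, saeS 0.43, SAOUHSC_00300 0.14, asp23 0.015, spoVG 0.45, sgtB 0.0387, lacE 0.41 and hrcA 0.16, without the filter saeR -0.0343, and with thinning agrC 0.0901 and spoVG 0.0584. Leaving out a library gave agrA -0.28 to 0.0173, agrC -0.21 to 0.11, saeR -0.30 to 0.29, saeS -0.29 to 0.14, sigB -0.25 to 0.37, SAOUHSC_00395 -0.0005 to 0.41, spoVG -0.21 to 0.0917, capD -0.83 to 1.42, SAOUHSC_00120 -0.52 to 0.56, arcD -0.0153 to 1.99, purA -2.88 to 1.09 and lacE -0.30 to 0.27, and adjusted p-values of 0.00474 to 0.651 for the capsule list, 0.000444 to 0.972 for the amino acid synthesis list and 0.751 to 0.946 for the agr list, which had 0.964 with DESeq2-style factors, 0.976 without the filter and 0.999 with the crossed block; the cause was not tested.

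Exchanging the library labels in compound 3 gave 388 changed genes (217 risen, 140 of the 388 shared). With the preset correlation it gave 2 lists (protein quality control 0.00032, toxins 0.00931). Exchanging them in DMSO gave 332 genes (242 risen, 87 of the 332 shared) and 3 lists. These were agr (0.0195), which was higher, and capsule and amino acid synthesis, which were both lower. Summing both libraries of each sample gave 481 genes (299 risen, 186 fallen, 111 shared) and 2 lists. Each count of genes is a median over 21 draws, so that they need not add up. The lists were capsule and amino acid synthesis, both lower, while agr had 0.0557. Of the 59 named genes past the threshold these settings lost 21, 21 and 16, and turned the sign of 0, 11 and 9. Reversed with labels exchanged in compound 3 were the lists of capsule 0.101, urease 0.438 and amino acid synthesis 0.0811 (adjusted p), and agrA 0.36, agrC 0.48, saeS 0.59, asp23 0.19, spoVG 0.32, capD -0.32, SAOUHSC_00120 -1.40, arcD -1.03, arcA -0.23, purL -0.30, purA -0.72 and lacR -0.52. With labels exchanged in DMSO they were the lists of capsule 0.00375, oxidative and thiol stress 0.0631, arginine deiminase 0.465, urease 0.128, amino acid synthesis 0.00375, ribosomal proteins 0.46, glycolysis 0.532 and TCA cycle 0.0506, and agrA 1.18, agrC 1.18, hld 0.58, spa 0.48, sarA 0.48, saeS 0.41, SAOUHSC_00300 0.56, ebpS 0.41, sbi 0.34, lytS -0.19, asp23 0.69, spoVG 1.22, capD -0.42, SAOUHSC_00120 -1.06, msrB 0.16, sgtB 0.94, pbp2 0.13, pflA 0.45, pflB 0.75, arcD -0.39, arcA -0.34, purL -0.74, purA -1.38, fbaA 0.28, acnA 0.015, sucD 0.36, lacR -0.57 and gyrB 0.0693. With summed libraries they were the lists of capsule 0.00839, oxidative and thiol stress 0.155, arginine deiminase 0.246, urease 0.152, amino acid synthesis 0.000411, glycolysis 0.901 and TCA cycle 0.171, and ureA -0.0923, agrA 0.87, agrC 0.93, hld 0.28, sarA 0.18, saeS 0.59, SAOUHSC_00300 0.0835, ebpS 0.15, lytS -0.24, asp23 0.55, spoVG 0.85, capD -0.50, SAOUHSC_00120 -1.30, msrB 0.24, sgtB 0.50, pbp2 0.0786, pflA 0.21, pflB 0.42, arcD -0.65, arcA -0.48, purL -0.73, purA -1.29, fbaA 0.17, sucD 0.14 and lacR -0.70; the cause was not tested.

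With 76765 to 102678 coding counts in the compound 3 libraries, depth limits what can be called, and edgeR recovered 7 of 100 simulated 2-fold changes.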

Other observations

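All tests on the chaperone genes, the tests on depth and on adjacent genes among the risen genes, the tests for an exchange of library labels and the runs of neighbouring loci were chosen only after the results were seen; the strand test of the risen genes was not.

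The fallen genes sat together on the chromosome. Among the 133 fallen genes 27 pairs were neighbours on the same strand, against a median of 8 in random draws of as many genes matched on mean count (one-sided permutation p = 0.0001, the smallest that 10000 draws can give). In 7 runs of 3 or more neighbouring changed loci, with 26 loci in all, 0 runs rose. The longest run, of 5, held the branched-chain 2-oxoisovalerate dehydrogenase genes SAOUHSC_01611, SAOUHSC_01612, SAOUHSC_01613 and SAOUHSC_01614, with log2 fold changes of -1.30, -1.44, -1.49 and -1.32, and recN at -1.34. The 4 pyruvate dehydrogenase genes SAOUHSC_01040, SAOUHSC_01041, SAOUHSC_01042 and SAOUHSC_01043 had -1.83, -1.17, -1.43 and -1.30, and prmA, next to dnaJ, dnaK and grpE, had -2.50. The other runs were mcsA, mcsB and clpC with SAOUHSC_00502 (-1.48), hlgA, hlgC and hlgB, and the hypothetical protein genes SAOUHSC_01675, SAOUHSC_01676 and SAOUHSC_01677 (-1.72, -1.95 and -2.23) and SAOUHSC_02566, SAOUHSC_02568 and SAOUHSC_02569 (-2.45, -1.45 and -1.71). Without DMSO replicate 2 the dehydrogenase genes other than SAOUHSC_01040 did not pass, with adjusted p-values of 0.14 to 0.386, nor did SAOUHSC_00502 (0.14) or SAOUHSC_02568 (0.122). Without DMSO replicate 1 SAOUHSC_01041, recN and the genes of the 2-oxoisovalerate dehydrogenase did not pass (0.0617 to 0.0948), and without compound 3 replicate 2 SAOUHSC_01612 had 0.0564. Over the settings without 1 library the log2 fold change of SAOUHSC_01042 ran from -2.04 to -1.02 and that of SAOUHSC_01612 from -2.25 to -0.96. In the TEX-treated libraries SAOUHSC_02568 and SAOUHSC_02569 rose by 0.95 and 1.97 on the log2 scale (edgeR adjusted p = 0.00704 and 2.54e-05). This is 0.13 below and 0.90 above genes of like expression. Of the 26 loci only dnaK, grpE and SAOUHSC_02566 were called lower there. With both libraries of each sample summed, 32 of the 133 fallen genes passed in the same direction.

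The fall of the chaperone and Clp protease genes was weighed against technical causes. Scaling or a trend with expression is argued against, since the list's median of -2.1353 lay below the central 95% range of 10000 random lists matched on mean count (-1.01 to 0.19). After thinning of the DMSO libraries the median was -2.1085 (range over draws -2.19 to -2.02). Random thinning keeps the expected ratio of the groups, so it could hardly shrink this median and does not decide whether depth played a part. In the TEX-treated libraries the list's median of -0.3309 lay below the same range of its random lists (0.30 to 1.35). Only dnaK, grpE and hrcA were called lower there, and clpP and clpX were called higher (clpP by no more than 0.0144 above genes of like expression). The interaction test called 12 of the 12 members. Random lists were drawn gene by gene, while members of this list vary together (estimated correlation 0.498), so their ranges are too narrow. An effect of the untreated libraries alone is therefore not excluded. The sum of both libraries of each sample gave the list a median of -1.067 (random lists -0.13 to 0.78). That value leans against an exchange of library labels in 1 group as the whole cause, by a range with the same limit. Lower levels of these transcripts relative to genes of like expression may be biological, as a hypothesis found and tested on the same 2 replicates, while the size of the fall stays open and no batch is given in the labels.

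The 99 risen genes, led by SAOUHSC_00979, SAOUHSC_02083 and SAOUHSC_01110, were weighed in the same way. Their median mean count was 57.5, against 36 for all tested genes. Background reads from both strands would raise antisense counts as well, but the antisense gain was -0.028 of the sense gain (95% bootstrap interval -0.138 to 0.003). The bootstrap resampled genes, so its interval leaves out variation between the 2 libraries of a group. These genes were also chosen for their sense gain in the same libraries, which can lower the share. After thinning of the DMSO libraries the median log2 fold change of these genes was 1.9057 (range over draws 1.79 to 1.95, and 1.92 before), and 58 of the 99 still passed the test. Random thinning keeps the expected ratio of the groups, so the median could hardly fall and does not decide whether depth played a part. The risen genes held 8 pairs of neighbours, against a median of 3 in matched random draws and 6 at their 95% bound (one-sided permutation p = 0.0134). Noise drawn separately for each gene would not give such an excess. Neighbours on the same strand may also vary together between samples, so the pairs do not tell a response from variation between samples. In the TEX-treated libraries 77 of the 97 risen genes with a value were higher with compound 3, and 69 stood above genes of like expression (95% range of chance 39 to 58). This leans against an exchange of library labels as the whole cause. The range takes genes as independent, which they are not, and the libraries come from the same samples. A response of these genes to compound 3 may underlie the rises, as a hypothesis from the same data, and the order of single genes among them stays uncertain.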
